A study of Homo sapiens with 5 samples.

How the data were processed

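Total RNA of HCT116 cells was hybridised to 5 single-colour Agilent arrays, 1 per group, labelled with Cy3. The groups were a negative control precursor, miR-34b and miR-34c (100 pmol, 48 h), mock (72 h) and DAC (2 µM, 72 h, renewed every 24 h), with groups from the sample titles and doses and times from the treatment protocols in the labels. Per the file headers, the deposited values are linear spot intensity from Agilent Feature Extraction 9.5 (9.5.1.1 in the headers), after background subtraction, spatial detrending and multiplicative detrending. Spots not above background hold surrogate values, per the file headers, and no step between arrays is recorded. Those files also give the mean spot signal and the local background as scanner intensity, per the file headers. The deposited value table holds the same processed intensity on a linear scale, rounded to 3 significant digits and within 0.497% of it, without centring. Its scale, centring and direction are therefore known. Its medians over all spots were 117, 67.4, 70.0, 105 and 144 for the negative control, miR-34b, miR-34c, mock and DAC.

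Each array held 45015 spots, of which 1639 were controls and were left out. The rest represented 41000 probes, 40736 spotted once and 264 spotted 10 times. Spots marked as outliers by Feature Extraction were removed, between 76 and 122 per array. The processed signal was put on the log2 scale, and each array's 75th percentile over non-control spots was subtracted. Spots of a probe were then averaged. A gene with several probes (7019 of 18091 genes) was represented by the probe brightest on average over the arrays. For 120 genes a dimmer probe was detected on an array where the brightest was not. Among genes with several probes and a difference of at least 2-fold, another measured probe had the opposite sign in 41 of 165 genes with miR-34b, 50 of 419 with miR-34c and 86 of 730 with DAC.

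Probe coordinates are those of the files, in hg17 (NCBI35). Gene symbols were updated through a RefSeq gene table of assembly GRCh38.p14, used for names only. Of 27538 probes with a symbol, 26794 matched that table and 744 kept the name in the file, and 13462 probes had no symbol.

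A probe was called detected on Agilent's flag for signals well above background. A gene detected on 1 of the arrays compared has only a bound: the brighter array against the higher of the dim probe's own signal and the lowest signal among detected probes, which was 32.4, 20.6, 16.8, 25.6 and 19.9 units in the order above. Such a bound is written "at least", and no fold was given below 1 or where neither array detected the gene. Genes were counted at a fixed 2-fold. The error of a log2 difference combines the spot errors in the files, near 10.1% per array, and covers neither cultures nor labelling. The number of arrays, 1 per group, limits the precision of every comparison, and no test across samples was possible. Counts of genes detected on both arrays that spot error alone would carry past 2-fold come from 100 simulations of unchanged arrays.

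The comparisons, the 2-fold limit, 20 gene lists, the rule for naming genes and the main alternatives were fixed before the data were examined. The lists were miR-34 targets named in earlier work, S phase and DNA replication, G2 and mitosis, p53 target genes, interferon-stimulated genes, cancer-testis and germline genes, genes with methylated promoters in colorectal cancer and the DNA methylation machinery. They went on with the BCL2 family and inhibitors of apoptosis, the amino acid and endoplasmic reticulum stress response, heat shock proteins, cholesterol biosynthesis, intestinal epithelial differentiation, mesenchymal genes, stromal and blood cell markers, Wnt pathway targets, immediate early genes, histone genes, the hypoxia response and housekeeping genes. Motile cilium genes and replication-dependent histones were added after the data had been seen. Each list's median is given with its percentile among 10000 random lists of the same size, drawn within 20 bins of mean expression, which describes these arrays and is no test.

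The rule for names took, per treatment, the 10 highest and 10 lowest genes detected on both arrays, at least 2-fold different and of the same sign with normexp, and the 3 largest bounds per direction. It also took the 2 highest and 2 lowest members of each list, 10 genes named in any case (CDK4, CDK6, CCNE2, MET, E2F3, MYC, BCL2, CDKN1A, DNMT1 and BTG4), the 10 genes per direction with the largest smallest difference over the treatments, and the 5 genes that differed most between the precursors in each direction. The text gives a selection of these genes. The 5 genes per direction for the negative control against mock, the comparison of probes without a symbol with the control arrays, and the definition of a turned sign for a named gene were set after the data had been seen.

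Correlations across genes have percentile intervals from 1000 bootstraps of genes. The effect of the shared control was simulated 100 times with unchanged arrays, and overlaps were set beside n1 × n2 / N. The procedure was tested on simulated data in which 50 genes per direction were changed 2.83-fold and 50 per direction 8-fold. Both simulated arrays were made from the control array with spot error alone. The changed genes were drawn only from genes more than 8-fold above that array's lowest detected signal, so recovery among dim genes was not tested. Of the 2.83-fold genes it called 98.0% of those higher and 100% of those lower for miR-34b (13218 genes), 100% and 96.0% for miR-34c (13223 genes) and all of them for DAC (13766 genes), and all 8-fold genes in each. Of unchanged genes, 0.138%, 0.0921% and 0.111% were called, including genes with a bound, which the counts from spot error leave out.

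Alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the array median or to the 75th percentile of probes detected on all arrays, and no filter on dim probes. Others were detection on every array of a comparison, the median of a gene's probes, the value table, mock as the control of miR-34c, and leaving out genes in the lowest quartile of signal. Scaling to 8 spike-in probes and leaving out the S phase and mitosis lists were added after the data had been seen. Analyses used R 4.3.3 with limma 3.58.1 for normexp, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Seed sites of miR-34 in transcripts were not analysed here, because transcript sequences were not used.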

Results

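Messenger RNA was profiled in HCT116, an established line of human colorectal cancer cells, on 5 single-colour Agilent arrays that covered the whole human genome. Cells were electroporated with 100 pmol of a precursor of miR-34b, of miR-34c or of a negative control RNA and sampled after 48 h. Other cells received 2 µM decitabine (DAC), an inhibitor of DNA methyltransferases, or PBS alone (mock) for 72 h, and the drug was renewed every 24 h. Both microRNAs belong to the miR-34 family, whose genes are transcribed by p53, and the design set the genes that responded to them beside those that responded to DAC. Each group had 1 array, so no difference has a replicate check or a p-value, and genes are called here only by size, as at least 2-fold higher or lower. The ± after a log2 difference is Agilent's error of the spots, not a spread between cultures. It comes from an error model with a multiplicative error of 10%, not from the spread of replicate spots.

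Between 61.1% and 70.0% of the 41000 probes were well above background. The number of genes detected was 12850 with the negative control, 12890 with miR-34b, 13225 with miR-34c, 13340 with mock and 14658 with DAC. The median processed signal was 130 units with the negative control, 74.97 with miR-34b and 77.5 with miR-34c, and 116 with mock and 157 with DAC. No spot was saturated. Spots of the same probe on an array had an SD of 0.0654 on the log2 scale. The negative control and both precursor arrays lay on slide 1, and the mock and DAC arrays on slide 2, so each treatment was compared with its control within a slide.

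The miR-34b precursor gave lower levels of CDK4, a kinase that drives cells from G1 into S phase, and higher levels of several p53 target genes, relative to the negative control. The log2 difference of CDK4 (probe on chromosome 12 at 56428530 to 56428589, hg17) was -1.93 ± 0.20, from a processed signal of 16040 units before scaling to 2512. Other genes among the 10 lowest were FGFRL1 (-2.54 ± 0.21), a receptor that binds fibroblast growth factors, HLA-DOB at -2.42, SPP1, which encodes osteopontin, at -2.04, the protease inhibitor SPINT1 at -1.93 and LIN54, a DNA-binding subunit of the DREAM complex, at -1.88. The highest were the pancreatic polypeptide gene PPY, 7.89-fold higher, DEPP1, 5.27-fold, and SUSD2, 5.07-fold, followed by CD4 (2.24), the decoy receptor TNFRSF6B (2.21) and the collagen gene COL13A1 (2.11). In total, 472 of 13172 genes were at least 2-fold higher and 175 at least 2-fold lower, of which 29 and 20 reached 4-fold. Among genes detected on both arrays, spot error alone would carry 3.76 past 2-fold. In simulated data that also held genes detected on 1 array, 0.138% of 13018 unchanged genes were called. Neither number covers differences between cultures. The negative control and mock arrays, which differ in electroporation, RNA transfer, time and slide, were at least 2-fold apart in 722 of 13585 genes. With miR-34b the number was 647 of 13172.

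Of 29 measured p53 target genes, 6 were at least 2-fold higher and 1 lower with miR-34b. Their median log2 difference was 0.54, above all 10000 random lists of the same size and expression (percentile 100). TP53INP1, an inducer of cell death and autophagy, was at 1.28 ± 0.20 and FDXR, the mitochondrial ferredoxin reductase, at 1.08, while CCNG1, cyclin G1, was at -1.46. The 39 genes of S phase and DNA replication had a median of -0.41 and the 36 genes of G2 and mitosis a median of -0.37, both at percentile 0. No S phase gene was lower by 2-fold, and the only such mitotic gene was the transcription factor FOXM1 at -1.19 ± 0.20. CCNE2, cyclin E2, was at -0.80 and MET, the receptor of hepatocyte growth factor, at -0.38. Of 26 genes named as miR-34 targets in earlier work, CDK4 was the only member at least 2-fold lower, 3 were higher, among them the apoptosis inhibitor BCL2 (1.14) and CD44 (1.11), and the median was -0.04 (percentile 5.03). CDK6, E2F3 and MYC were at -0.11, 0.01 and 0.31.

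Immediate early genes, which respond to growth factors, had 4 of 17 members higher with miR-34b, including EGR1 at 1.28, and a median of 0.47 (percentile 99.6). Interferon-stimulated genes had 2 of 24 higher, the transcription factor IRF7 (1.26) and the RNA sensor RIGI (1.12), and a median of 0.39 (percentile 99.9). The BCL2 family and inhibitors of apoptosis had 3 of 15 higher, with BIRC3 at 1.33 and HRK at 1.31, and a median of 0.44 (percentile 99.4). Genes with methylated promoters in colorectal cancer had 3 of 19 higher, with TMEFF2 at 1.65 and NEUROG1 at 1.54, and a median of 0.35 (percentile 98.6). Genes of intestinal epithelial differentiation had a median of 0.51 (percentile 98.4). In the negative control against mock their median was -0.35 (percentile 1.36), so a low control array may contribute. The other 12 lists lay within the central 95% of random lists. Their medians were -0.02 for cancer-testis and germline genes, -0.07 for the DNA methylation machinery, 0.18 for the amino acid and endoplasmic reticulum stress response, 0.36 for heat shock proteins and 0.31 for cholesterol biosynthesis. They were 0.32 for mesenchymal genes, 0.21 for stromal and blood cell markers, 0.01 for Wnt pathway targets, 0.37 for histone genes, 0.06 for the hypoxia response and 0.12 for housekeeping genes, which were at -0.35 (percentile 0.03) with quantile normalization. Histone genes lay outside with normexp, quantile normalization and the median of a gene's probes (percentiles 98.0, 98.5 and 98.8), and cholesterol biosynthesis with the last 2 (99.4 and 98.5).

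SLURP1 was at least 17.1-fold higher with miR-34b, and AMHR2 at least 12.03-fold and CLCN4 at least 11.3-fold, as bounds against a control signal not well above background. In the other direction the bounds were at least 7.95-fold for FLJ34047, 6.70-fold for CYP2C18 and 6.53-fold for FLJ12151, and these 3 were well above background on the negative control array alone, at 275, 231 and 225 units. Of the genes called, 73.0% were higher with the main scaling, 58.5% with scaling to probes detected on all arrays and 24.8% with scaling to spike-in RNA. With normexp background correction DEPP1 (0.97), CLCN4 (0.97), AMHR2 (0.86) and RIGI (0.93) were under 2-fold, and the intestinal list had a median of -0.03. FDXR (0.74) and CD44 (0.91) were under 2-fold with quantile normalization, HRK (0.73) and IRF7 (0.898) with the median of a gene's probes and BCL2 (0.86) with spike-in scaling, and the BCL2 family had percentile 95.7 with quantile normalization and genes with methylated promoters 80.1 without the filter on dim probes.

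With miR-34c the same directions held for CDK4 and the p53 target genes, and genes of the cell division cycle were much lower. Of 39 S phase genes, 34 were at least 2-fold lower, with a median of -1.66, and of 36 genes of G2 and mitosis, 33 were lower, with a median of -2.01 (both at percentile 0). MKI67, the proliferation marker Ki-67, was lowest of the genes detected on both arrays at -3.08, which is 8.47-fold. The mitotic kinase AURKB was at -2.78 ± 0.21, KIF20B at -2.71, GTSE1 at -2.65, FOXM1 at -2.62 and the mitotic kinesin KIF11 at -2.55. CCNA2, cyclin A2, was at -2.42, the ribonucleotide reductase subunit RRM2 at -2.40 and CCNE2 at -2.01. CDK4 was at -1.16 ± 0.20 and MET at -0.98. In total, 1050 of 13433 genes were at least 2-fold higher and 678 at least 2-fold lower, against 3.10 from spot error alone among genes detected on both arrays, and 97 and 115 reached 4-fold.

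SUSD2, a membrane protein, was the highest with miR-34c of the genes detected on both arrays, 24.0-fold above the negative control. CBS, cystathionine beta-synthase, was 15.1-fold higher, KRTAP3-1 14.2-fold, QPRT, an enzyme of NAD synthesis, 8.56-fold, and the adhesion molecule CEACAM1 7.66-fold. The 10 highest also held DNAI3, a dynein subunit of motile cilia, at 13.3-fold, and the ciliary genes RSPH1 at 7.77-fold, ROPN1L at 7.45-fold and CFAP251 at 7.36-fold. Bounds were at least 20.9-fold for SLURP1, 16.4-fold for AMHR2 and 15.1-fold for FBLN7. The largest bounds in the other direction, at least 9.78-fold, 8.25-fold and 8.03-fold, were again those of FLJ34047, CYP2C18 and FLJ12151.

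Of 30 p53 target genes, 16 were at least 2-fold higher with miR-34c and none lower, with a median of 1.03 (percentile 100). TP53INP1 was at 2.40 ± 0.20, TP53I3 at 2.34 and CDKN1A, the inhibitor p21 of cyclin-dependent kinases, at 1.57 ± 0.20, against 0.32 with miR-34b. Interferon-stimulated genes had 12 of 25 higher and a median of 0.99 (percentile 100), with RIGI at 1.89 and IFI27 at 1.88. Immediate early genes had 10 of 18 higher and 1 lower, with a median of 1.25 (percentile 100), EGR2 at 2.97, the phosphatase DUSP6 at 2.07 and KLF4 at -1.13. The miR-34 targets named in earlier work had a median of -0.45 (percentile 0), with 4 of 26 lower, including FOSL1 at -1.48, and 2 higher, MYCN at 1.26 and CD44 at 1.03. BCL2 was at 0.82, MYC at 0.66, E2F3 at 0.08 and CDK6 at -0.07.

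The BCL2 family had a median of 0.72 (percentile 99.96) with 1 of 16 members higher, HRK at 1.20. Intestinal genes had a median of 0.79 (percentile 99.9) and 3 of 12 higher, with the keratin KRT18 at 1.36. Their median of -0.35 in the negative control against mock (percentile 1.36) leaves open that a low control array contributes. Histone genes had a median of 0.62 (percentile 99.2), with H2AC18 at 2.48 and H2BC5 at -1.32. Housekeeping genes had a median of -0.11 (percentile 0.32), which was 0.11 with normexp. The DNA methylation machinery lay at -0.19 (percentile 4.57), within the central 95% of random lists. Its members included the chromatin remodeller HELLS at -2.35, UHRF1 at -1.36 and DNMT1, the maintenance methyltransferase, at -0.91 ± 0.20. The other 9 lists also lay within the central 95%. Medians were 0.22 for cancer-testis and germline genes, 0.37 for genes with methylated promoters, 0.10 for the amino acid and endoplasmic reticulum stress response, 0.37 for heat shock proteins and 0.00 for cholesterol biosynthesis. They were 0.10 for mesenchymal genes, 0.36 for stromal and blood cell markers, 0.13 for Wnt pathway targets and 0.35 for the hypoxia response. Cholesterol biosynthesis lay outside with normexp (-0.07, percentile 1.80) and methylated promoters without the filter on dim probes (percentile 98.4). With normexp CDK4 (-0.98), KLF4 (-0.9996) and EGR2 (0.87) were under 2-fold, and the intestinal list had percentile 91.2. CD44 (0.80) and KRT18 (0.74) were under 2-fold with quantile normalization, HRK (0.88) and H2BC5 (-0.03) with the median of a gene's probes and MYCN (0.95) with spike-in scaling. Of the genes called with miR-34c, 60.8% were higher with the main scaling and 25.6% with spike-in scaling, while scaling to detected probes gave 823 higher and 823 lower.

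The responses to the microRNAs were then compared with each other. Across 12494 genes detected on all 3 arrays, the log2 differences correlated with Pearson's r of 0.73 (bootstrap over genes, 0.72 to 0.74) and Spearman's rho of 0.75, although genes are not independent replicates. Both used the same control array, which alone gave r of 0.50 between unchanged simulated arrays. The covariance was 0.22 against 0.024 in the simulation, a difference of 0.20. With mock as a separate control of miR-34c, r was 0.55 and the covariance 0.21, and with mock as that of miR-34b they were 0.61 and 0.25. Mock also differs from the negative control in electroporation, RNA transfer, time and slide. Genes higher with both numbered 308, against 32.5 for independent lists and 0.26 in simulations of the shared control. Genes lower with both numbered 106, against 9.09 and 0.22. The simulations hold only the genes detected on all 3 arrays, whereas 308 and 106 include bounds. With detection required on every array the counts were 295 and 56. In place of 308 and 106, the counts were 197 and 57 with mock as the control of miR-34c, and 85 and 354 with spike-in scaling. No gene was at least 2-fold higher with either and at least 2-fold lower with the other, where independent lists would share 22.4 and 13.2. With a shared control, such opposite calls need the precursor arrays to be at least 4-fold apart. Only 26 genes were that much higher with miR-34b than with miR-34c and 38 lower. Few opposite calls were thus possible, and the counts for independent lists are no fair yardstick. Part of the excess in the same direction may come from the shared control array. Its simulations hold spot error alone and do not cover differences between cultures.

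**Figure D1:**
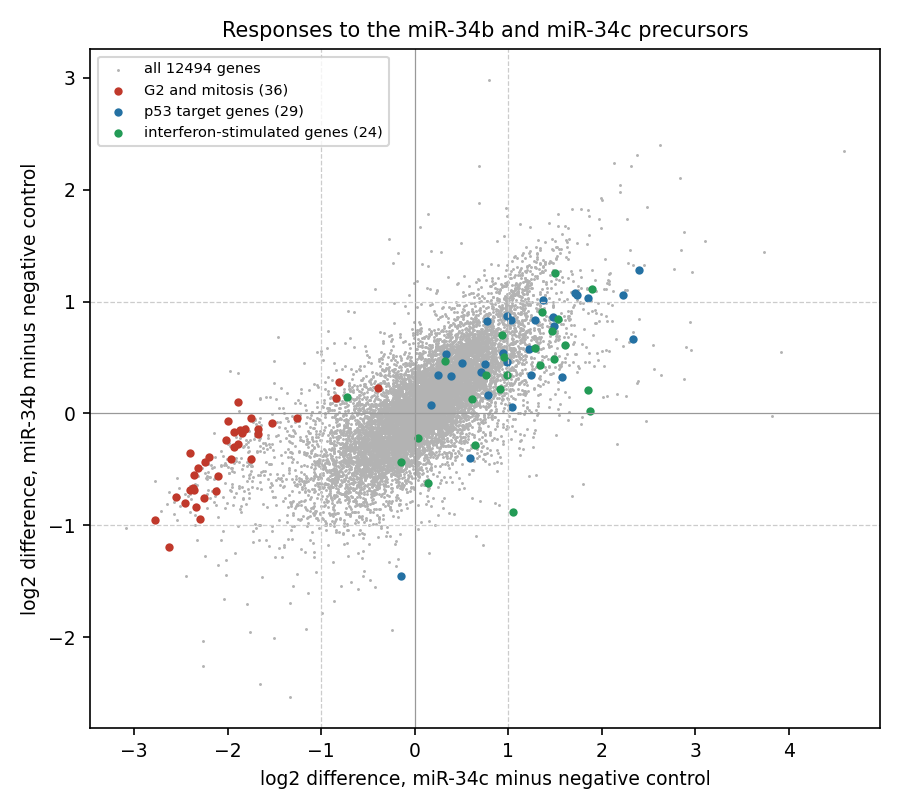
Log2 difference from the negative control with miR-34c (horizontal axis) and with miR-34b (vertical axis) for 12494 genes detected on all 3 arrays, 1 point per gene, with dashed lines at 2-fold and 3 gene lists in colour. The genes of G2 and mitosis have a median of -2.01 with miR-34c and -0.37 with miR-34b, and the p53 target genes have medians of 1.03 and 0.54.

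Compared directly, 415 of 13396 genes were at least 2-fold higher with miR-34b than with miR-34c and 333 lower. The genes of G2 and mitosis were higher with miR-34b by a median of 1.66 and the S phase genes by 1.31 (both at percentile 100), with 34 of 36 and 30 of 39 at least 2-fold. Cholesterol biosynthesis genes had a median of 0.42 (percentile 100) with 1 of 19 at least 2-fold higher, and the miR-34 targets named in earlier work 0.20 (percentile 99.9) with 3 of 26. The p53 target genes had a median of -0.62, interferon-stimulated genes of -0.69 and immediate early genes of -0.67 (all at percentile 0), with 5 of 30, 3 of 25 and 6 of 18 at least 2-fold lower with miR-34b and 1 immediate early gene higher. CDK4 went the other way from the division genes, lower with miR-34b by -0.76 ± 0.20. The genes that differed most in favour of miR-34b were the interleukin 6 receptor IL6R (2.35), the kinetochore gene SPC25 (2.25), PPY (2.18), WDR76 (2.17) and C6orf141 (2.14). In favour of miR-34c they were KRTAP3-1 (-3.84), CBS (-3.37), CFAP251 (-2.57), CATSPERQ (-2.54) and CEMIP (-2.44).

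DAC gave high levels of genes of the germ line and of the interferon response relative to mock. The transketolase-like gene TKTL1 (probe on chromosome X at 153079471 to 153079530, hg17) was 2069-fold higher, from 36.0 units with mock to 79410 with DAC, a log2 difference of 11.02. The cancer-testis genes GAGE12F and CT45A5 were 1085-fold and 474-fold higher, the germ cell gene DAZL 146-fold and TDRD12 127-fold. IFI27 was 282-fold and the antiviral GTPase MX1 145-fold higher, and TXNIP, an inhibitor of thioredoxin, had a log2 difference of 7.59. Bounds were at least 2109-fold for XAGE1, 1129-fold for CTAG1A and 1040-fold for UCHL1, a neuronal ubiquitin hydrolase. Near-identical copies of the GAGE, CT45, XAGE and CTAG families cannot be separated by these probes. In total, 2552 of 14900 genes were at least 2-fold higher and 1139 lower, against 3.03 from spot error alone among genes detected on both arrays. Of those higher, 434 reached 8-fold and 916 were bounds.

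Of 34 cancer-testis and germline genes measured, 29 were at least 2-fold higher with DAC and none lower, with a median of 3.91, which was 2.14 over the 13 detected on both arrays and 2.52 with normexp. Interferon-stimulated genes had 27 of 30 higher and none lower, with a median of 3.42, and p53 target genes 17 of 30 and none lower, with a median of 1.20 (all 3 lists at percentile 100). TP53INP1 was at 3.49, TP53I3 at 3.12 and CDKN1A at 2.15 ± 0.20. Genes with methylated promoters in colorectal cancer had 14 of 30 higher and 2 lower, with a median of 0.96 (percentile 99.98) and VIM, vimentin, at 5.85, while the repair gene MGMT was at -1.28. Over the members of that list detected on both arrays the median was 0.40 (percentile 97.4, within the central 95%). Mesenchymal genes had 8 of 10 higher and a median of 1.99 (percentile 99.97), with SPARC at least 75.1-fold higher. Markers of stromal and blood cells, which an HCT116 culture should lack, had 7 of 11 higher and a median of 1.47 (percentile 99.7), with VWF at 3.11 and HBA1 at 3.09. Histone genes had 8 of 12 higher and 2 lower, with a median of 1.60, H2AC18 at 6.38 and H2BC5 at -2.74. Immediate early genes had 10 of 18 higher and a median of 1.32, with the matricellular gene CCN2 at 5.43 and ATF3 at 3.34 (both lists at percentile 100).

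The division cycle genes were lower with DAC. Of 39 S phase genes, 33 were at least 2-fold lower, with a median of -1.62, and of 36 genes of G2 and mitosis, 27 were lower, with a median of -1.30 (both at percentile 0). KIF11 was at -2.88 ± 0.21, MKI67 at -2.85, CCNA2 at -2.40, CCNE2 at -2.38 and CDK4 at -1.59. Among the 10 lowest measured genes were the transcription factor MKX (-3.62), the ciliary gene ODAD2 (-3.42) and the histone H4 genes H4C2 (-3.42), H4C13 (-3.39) and H4C4 (-3.15). The list also held NEXN (-3.22), MTUS2 (-3.23) and GDF10 (-3.11), and 2 Y-linked genes whose values are not reported. Bounds were at least 15.7-fold lower for GPR27, 14.02-fold for HCAR3 and 12.8-fold for ERVFRD-1. DNMT1, whose protein DAC traps on DNA, had an mRNA difference of -1.06 ± 0.20, and MET was at -0.92, MYC at -0.88 and BCL2 at -0.22. E2F3 was at -0.65 and CDK6 at 0.33. BTG4, the neighbour that shares a CpG island with the miR-34b/c locus, was not well above background in the other arrays and was at least 1.25-fold higher with DAC.

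The miR-34 targets named in earlier work had a median of -0.35 with DAC (percentile 1.15), with 5 of 27 lower, including FOSL1 at -1.88, and LEF1 at least 7.31-fold higher. Heat shock proteins had a median of -0.52 (percentile 1.99), intestinal genes 0.61 (percentile 97.8, 7 of 16 higher, 1 lower and KRT20 at 3.80) and the amino acid and endoplasmic reticulum stress response 0.30 (percentile 98.3, 4 of 18 higher, 2 lower, with CTH at 2.42 and PHGDH at -2.14). The remaining lists lay within the central 95% of random lists, with medians of -0.02 for the DNA methylation machinery, -0.09 for the BCL2 family, 0.09 for cholesterol biosynthesis, -0.07 for Wnt pathway targets, 0.41 for the hypoxia response and -0.27 for housekeeping genes. The hypoxia response lay outside with normexp (percentile 98.1) and quantile normalization (97.6). Of the genes called with DAC, 69.1% were higher with the main scaling, 58.6% with quantile normalization and 43.9% with scaling to the array median, which put the median of all genes at -0.35 and the stress list at -0.03. The miR-34 target and intestinal lists had percentiles of 17.3 and 94.5 without the filter on dim probes, and the intestinal list 96.3 over members detected on both arrays and 90.7 with normexp. The miR-34 target list had percentile 3.86 with quantile normalization. With the median of a gene's probes, NEXN (-0.74), GDF10 (-0.79) and H2BC5 (-0.24) were under 2-fold and heat shock proteins, the miR-34 target list and the stress list had percentiles of 2.88, 10.2 and 95.5. DNMT1 (-0.99) was under 2-fold with scaling to detected probes.

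**Figure D2:**
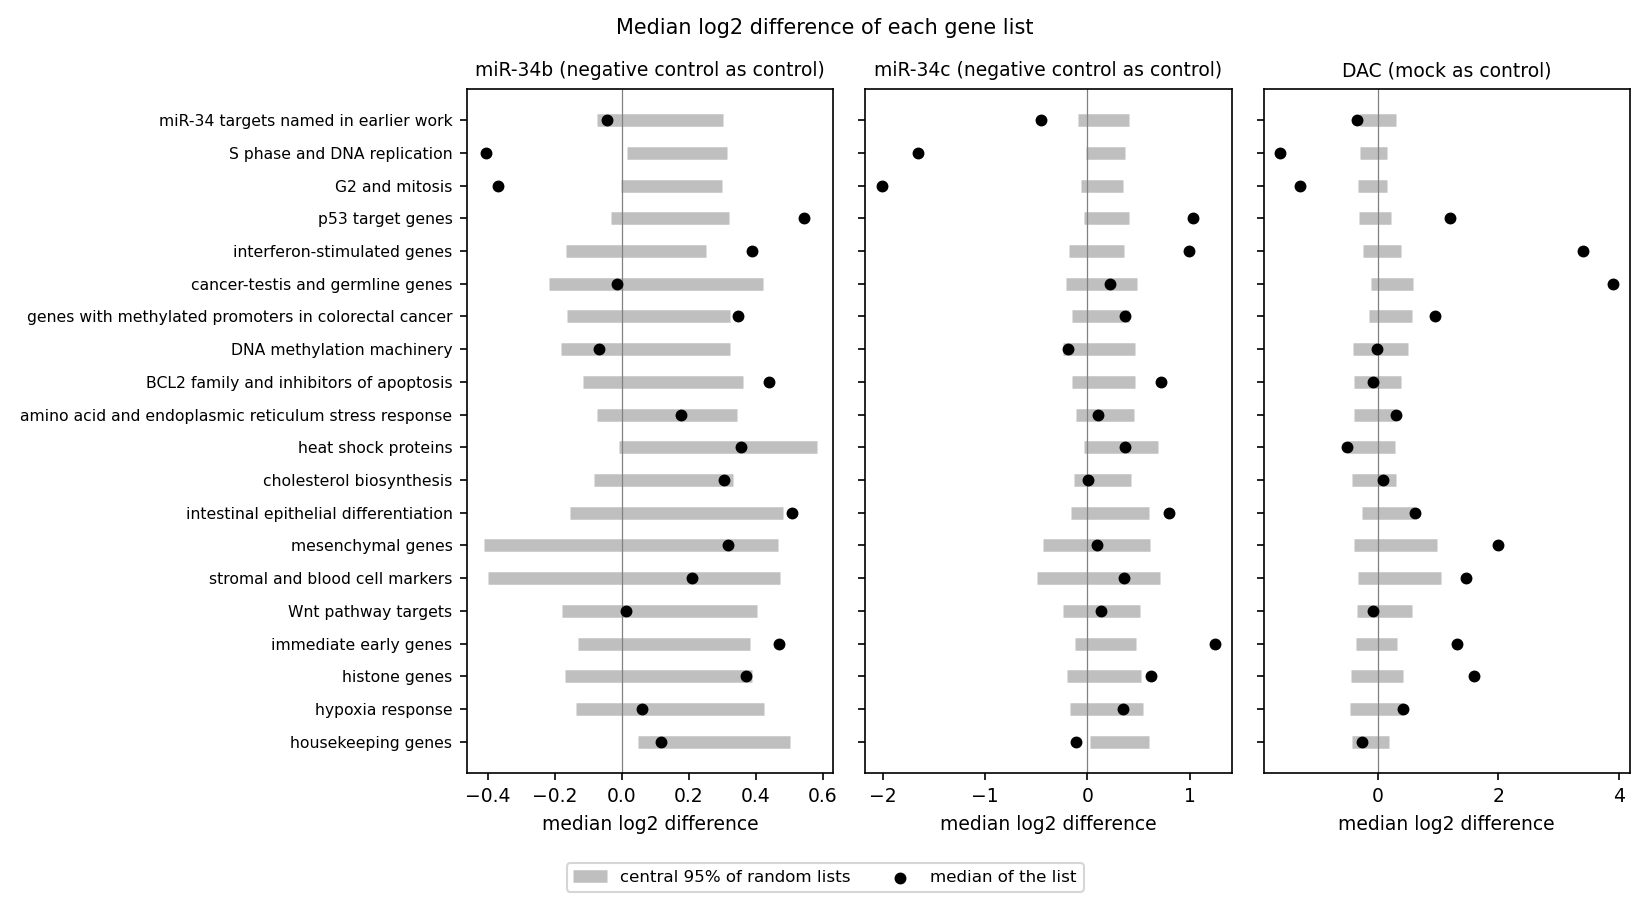
Median log2 difference (horizontal axes, 1 scale per panel) of the 20 gene lists with miR-34b and miR-34c against the negative control and with DAC against mock; points are medians of 1 array against 1 array, and grey bars hold the central 95% of 10000 random lists matched on expression. The S phase and the G2 and mitosis lists lie left of the grey bars in each panel, and the p53 target and interferon-stimulated lists lie right of them.

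The genes shared between the microRNAs and DAC were those at least 2-fold different in the same direction in all 3 comparisons. Of 302 genes higher with both precursors and tested with DAC, 99 were also higher with DAC, against 39.4 for independent lists, and none was lower, against 23.7. Those with the largest smallest difference included DEPP1 (2.40, 2.63 and 2.43 with miR-34b, miR-34c and DAC), SUSD2 (2.34, 4.59 and 2.21), COL13A1 (2.11, 2.83 and 2.21), the nuclease ISG20 (1.74, 2.27 and 3.13) and the arrestin-like gene ARRDC4 (1.74, 1.97 and 2.23). With normexp DEPP1 (0.97) and ARRDC4 (0.95) were under 2-fold with miR-34b. H2AC18 was at 1.85, 2.48 and 6.38. Of 91 genes lower with both precursors and tested with DAC, 30 were lower with DAC, against 7.13, and 23 were higher, against 11.9. The counts shared by all 3 comparisons, 99 higher and 30 lower, were 43 and 10 with normexp, 30 and 96 with spike-in scaling and 185 and 50 without the filter on dim probes. The shared lower genes included the nucleoside transporter SLC29A1 (-1.66, -2.04 and -1.67), MNS1 (-1.71, -1.79 and -1.78), the nuclear pore gene NUP210 (-1.36, -2.10 and -2.57), the ubiquitin ligase adaptor DTL (-1.31, -2.02 and -1.93), MYB (-1.27, -2.24 and -1.48) and FOXM1 (-1.19, -2.62 and -2.24).

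miR-34c and DAC shared more genes than miR-34b and DAC did. Of 1015 genes higher with miR-34c and tested with DAC, 441 were higher with DAC (138.5 for independent lists). Of 654 genes lower with miR-34c and tested with DAC, 303 were lower with DAC (50.7). The S phase and mitosis lists held 59 of those 303. For miR-34b the shared counts were 130 of 439 higher genes (57.7) and 36 of 160 lower genes (12.5), again of those tested with DAC. Across 12373 genes detected on all 5 arrays, the mean log2 difference of the precursors correlated with that of DAC with Pearson's r of 0.43 (bootstrap over genes, 0.41 to 0.45), Spearman's rho of 0.43 and a covariance of 0.21. Pearson's r was 0.46 for miR-34c and 0.31 for miR-34b, and 0.41 for the mean without the S phase and mitosis lists. These comparisons have separate controls on separate slides. The negative control against mock, which shares the mock array with DAC, had r of 0.30 with DAC and a covariance of 0.12, against 0.023 from spot error alone in simulations of the shared array, which do not cover differences between cultures.

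**Figure D3:**
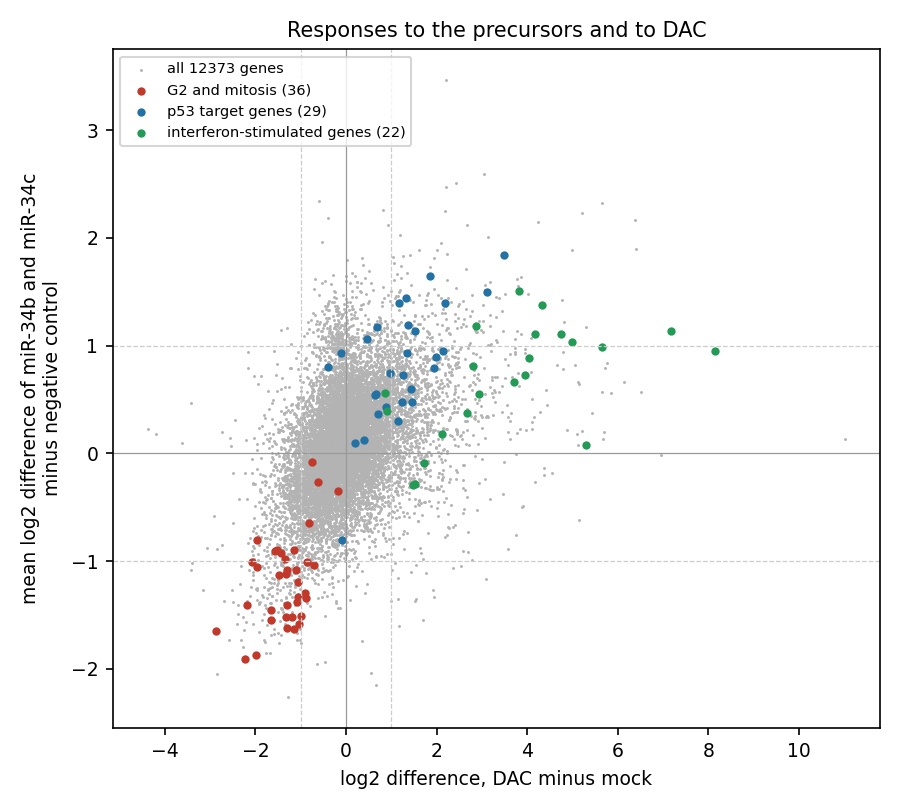
Log2 difference of DAC from mock (horizontal axis) and mean log2 difference of miR-34b and miR-34c from the negative control (vertical axis) for 12373 genes detected on all 5 arrays, 1 point per gene, with dashed lines at 2-fold and 3 gene lists in colour. The genes of G2 and mitosis lie mostly at the lower left, and the interferon-stimulated genes extend furthest right among the lists, to 8.14 for IFI27.

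The negative control and mock arrays differed in electroporation, in RNA transfer, in time and in slide, which cannot be told apart. Interferon-stimulated genes had a median of 0.61 in the negative control (percentile 100), with IFIT1 at 2.44, and p53 target genes of 0.41 (percentile 100), with 6 of 26 and 2 of 29 members at least 2-fold higher. The natural killer cell receptor genes KLRC1, KLRC2 and KLRC3, neighbours on chromosome 12, were higher by 2.44, 2.37 and 2.93. Heat shock proteins had a median of -0.47 and S phase genes of -0.25 (both at percentile 0), with 0 of 9 and 1 of 39 members at least 2-fold lower. The miR-34 targets named in earlier work had a median of -0.20 (percentile 1.42, 2 of 26 lower and 1 higher) without either precursor, and intestinal genes of -0.35 (percentile 1.36, 2 of 14 lower). Cholesterol biosynthesis had a median of 0.28 (percentile 99.9, 1 of 19 higher) and histone genes of 0.30 (percentile 99.2, 3 of 12 higher). Of the 20 lists, 8 lay outside the central 95% of random lists, as many as with miR-34b. The lowest genes were RFPL2 (-3.46) and KRT7 (-3.20). In total, 340 of 13585 genes were at least 2-fold higher in the negative control and 382 lower. The share higher was 47.1% with the main scaling, 14.8% with spike-in scaling and 95.6% with normexp.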

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

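The comparison in this part was chosen after the counts had been seen. Probes without a gene symbol were outside all counts of genes, and these also differed between arrays. With miR-34b, 678 of 6803 such probes tested were at least 2-fold different, with miR-34c 1047 of 7102 and with DAC 1799 of 7740. The negative control against mock, a pair without either treatment, gave 663 of 7135. The number for miR-34b was thus close to that between the control arrays. No gene names or explanation were sought for these probes.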

How the results depend on the processing

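Spike-in scaling was chosen after the result was seen. No paired analysis was possible because each group had 1 array and no result comes from a test. The analysis of seed sites was not run, since no transcripts were used here. Signal over background limits the bounds, which rest on the lowest detected signal of each array. Counts refer to genes at least 2-fold different, and the cause of a moved value was not tested except where the alternative adds or removes genes.

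Without the filter on dim probes, which adds genes, 870 were higher and 452 lower with miR-34b (472 and 175 with the filter), 1583 higher with miR-34c (1050), 480 higher and 261 lower with both (308 and 106), and 185 higher and 50 lower in all 3 comparisons (99 and 30). The precursors then differed in 1444 genes (748) and the controls in 1761 (722), and r was 0.62 between the precursors (0.73) and 0.22 between precursors and DAC (0.43). With detection required on every array, which removes genes, 114 were lower with miR-34b, 56 lower with both, 1636 higher with DAC (2552) and 453 different between the controls. With normexp, 662 were higher with miR-34c, 1662 higher with DAC, 391 different between the precursors, and 43 higher and 10 lower in all 3, with r of 0.79 and 0.25. With spike-in scaling, 178 were higher and 539 lower with miR-34b, 460 higher and 1339 lower with miR-34c, 85 higher and 354 lower with both, and 30 higher and 96 lower in all 3. It put the median of all genes at -0.20 with miR-34b, -0.19 with miR-34c and -0.31 for the negative control against mock. With array median scaling, 2311 were lower with DAC (1139). The r between precursors and DAC was 0.46 with quantile normalization and 0.49 without genes in the lowest quartile of signal. With mock as the control of miR-34c, r between the precursors was 0.55, and 197 genes were higher and 57 lower with both.

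The other 140 summary values stayed within 1.5 times or within their interval. Among list medians and named genes, 6748 values stayed on their side of the limit (2-fold, or the central 95%), 172 lost it and 102 gained it. Where the main setting lay within the limit, the sign turned in 42 list medians and 219 values of named genes, with housekeeping genes at -0.35 (percentile 0.03) with miR-34b under quantile normalization. Under normexp, for example, stromal markers lay at -0.52 with miR-34b and -0.60 with miR-34c and mesenchymal genes at -0.20 with miR-34b. Of named genes that lost the limit, 51 did so with normexp, where ATP6V0A4 and LGALS4 with miR-34b and TGFBI with miR-34c had no fold. Of results past the limit, signs turned for the intestinal list (-0.03) with miR-34b and housekeeping genes (0.11) with miR-34c under normexp, and for the stress list with DAC (-0.035) under array median scaling. They also turned for EGR2 (-0.20), QPRT (-0.024) and SPAG4 (-0.22) with miR-34b under normexp, and for GEN1 (0.15) with miR-34c under the median of its probes.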

Other observations

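The tests on the brightness of the miR-34b array and on the background of the DAC array, both added lists, the shares by chromosome and the splits by signal other than that under median scaling were chosen after the result was seen. The planned bounds against signals near background and the scaling with DAC were met, but these explanations were reopened after the result was seen, for the reasons given below.

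Replication-dependent histone genes, which normally yield mRNA without a poly(A) tail, went both ways with DAC. Of 42 measured, 19 were at least 2-fold higher and 6 lower, with a median of 0.84 (percentile 100). Without the 4 members seen beforehand the median was 0.96, with 19 of 38 higher and 2 lower. The 4 members left out were all among the 6 lower, so leaving them out could only raise the median. The lower side thus rests mainly on members seen beforehand. H2AC7 was at 4.82 and H1-3 at 3.98, whereas the H4 genes H4C2 and H4C13 were at -3.42 and -3.39. With miR-34c, 10 of 41 were higher and 6 lower (median 0.09, percentile 35.7), with H2BC9 at 1.52 and H4C4 at -1.88. With miR-34b, 1 of 40 was higher (median 0.22, percentile 96.0).

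Genes on the X chromosome, where many cancer-testis genes lie, were more often higher with DAC than autosomal genes. At least 2-fold higher were 25.8% of 547 X-linked genes and 16.8% of 14272 autosomal genes, and at least 8-fold higher were 11.2% and 2.59%. Near-identical copies of cancer-testis genes with their own symbols counted as separate genes, and no share was computed without them. Among the autosomes the largest share at least 2-fold higher was on chromosome 19, 21.9%, and the largest at least 8-fold higher on chromosome 21, 5.62% of 160 genes.

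Genes of motile cilia were higher with miR-34c. Of 43 measured, 17 were at least 2-fold higher and 3 lower (median 0.69, percentile 100), led by DNAI3 at 3.74 and RSPH1 at 2.96, while SPAG6 was at least 4.88-fold lower. Signals near background are argued against, since members not seen beforehand and detected on both arrays had percentile 100, and so is the choice of the list, since its unseen members had percentile 99.98. A loss of dividing cells stays open and may account for it: with DAC, where mitotic genes were also lower, the list had percentile 98.76, but its unseen members had 90.4. The unseen members were also at percentile 99.88 in the negative control against mock, where the mitosis list was at -0.09, and at 58.7 with miR-34b.

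The genes of G2 and mitosis were lower with miR-34c than with miR-34b by 1.66. A dimmer miR-34b array is argued against, since the 75th percentiles of the precursor arrays differed by a ratio of 1.007. Fewer cells taking up the miR-34b precursor is argued against as the sole cause only if both microRNAs lower CDK4 alike in each cell. That was not tested. CDK4, named beforehand as the gauge, was lower with miR-34b than with miR-34c by -0.76 ± 0.20, which lower uptake alone would then not give. The residual of 1.663 adds nothing to this, since the share from CDK4 (1.33) was held at 1 and the prediction was the miR-34c values. CDK4 is a single gene and was also lower with DAC, where no precursor was given. The 504 other genes lower with miR-34c implied a share of 0.49, but choosing them for low values with miR-34c favours a low share. The mitotic genes implied 0.28, which restates the difference itself, so neither share can decide on uptake. Some difference in uptake stays open, as does a difference between the microRNAs, which 1 array each cannot test.

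With DAC, dim genes were more often at least 2-fold higher than bright genes, but whether they were also more often lower depended on the scaling. Of the dimmer and the brighter 7450 genes, 26.2% and 8.05% were higher and 7.26% and 8.03% lower with the main scaling, against 20.9% and 9.13% higher and 13.9% and 7.26% lower with quantile normalization. Among genes detected on both arrays, the dimmer 6547 were 17.6% higher and 7.22% lower with the main scaling, and 14.1% and 13.3% with quantile normalization. Negative control spots differed by -0.146 between the DAC and mock arrays in processed signal, after background subtraction. Of 153 such spots, 0 with DAC and 2 with mock were well above background, so surrogate values may hide a higher background. Only 3 dim spike-in probes, at -0.13 to 0.07, argue against a higher background left in the processed signal. A higher background before subtraction was not tested. Signals near background and the scaling may contribute and stay open: the planned ratio of 1.638 genes higher per gene lower, detected on both arrays, includes bright genes, and median scaling, with 4.377 between the shares, shifts all genes alike.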
